A study of Mus musculus with 4 samples.

How the data were processed

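The series holds 4 single-channel arrays of total RNA from the dentate gyrus of handled control mice, 1 for each of 1, 2, 4 and 6 h. The authors deposited a table of intensity values on a linear scale, 1 column per array and 1 row per probe set. The labels name no software, scaling target or detection call, so how the authors made the intensity values is not given in the sources used here. From the values alone, the 2%-trimmed mean over all rows of the deposited table was 500.3 in each array. Over the 12422 probe sets that are not controls it was 496, 496, 496 and 496 to the nearest whole number, and the medians were 183, 182, 184 and 169 at 1, 2, 4 and 6 h. With a common trimmed mean, a difference in total RNA between samples does not show in these values.

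The table has 12488 rows, of which 66 are control probe sets and were left out of tests. Gene names came from the array annotation supplied for this work, with symbols updated through Entrez identifiers in a table of the GRCm38.p6 assembly. That table was used for names only, and no coordinates are given because the sources used here name no genome build. Exactly 1 gene named 10833 probe sets (8251 genes), several genes 396 and none 1193, and no gene is named from the latter groups. Probe sets whose identifiers end in _f_at, _s_at, _r_at, _i_at or _g_at can share sequence with related genes or rest on fewer probes, so their values are less certain. Probe sets of the same gene were kept apart.

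Values were used as deposited because the trimmed means lay within 5% of each other. Values under the 10th percentile of the non-control values, an intensity of 16.4, were set to it, and log2 was taken. Between 1056 and 1462 probe sets per array lay under that floor. A probe set was kept for tests when its mean log2 value reached the 40th percentile (6.66), which left 7453 probe sets, 6734 of them named by 1 gene. The deposited values give no read depth, and the number of arrays limits the precision.

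The trend was a linear fit of log2 intensity on the hour with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean intensity), with 2 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05 over 7453 probe sets. Tests are two-sided. Gene lists were tested on the same slope with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The latter 2 rest on the few residual degrees of freedom, and their power was not simulated, so not passing them says little about a list. A list needed 5 kept probe sets. The 23 lists were immediate early, activity-induced effector, glucocorticoid-responsive, circadian clock, heat shock and chaperone, granule cell, CA pyramidal, interneuron, astrocyte, oligodendrocyte, microglia and macrophage, endothelial and mural, choroid plexus and ependymal, meningeal and fibroblast, thalamic and striatal, erythrocyte, immature neuron and proliferation, oxidative phosphorylation, cytosolic ribosomal protein, glutamate receptor, GABA-A receptor, synaptic vesicle and release, and sex-linked genes. The erythrocyte list kept 4 probe sets and the sex-linked list 1, so 21 were tested. Some genes stand in several lists, such as Per1, Igf2 and Nnat. A list's median in an array was set among 10000 random lists matched on mean intensity in 10 bins (seed 1). Differences between hours have no test, and probe sets at least 2-fold apart were counted.

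The lists, tests, settings and the rule for named genes were fixed before the data were examined. The rule names the 10 probe sets of largest slope in each direction that passed the test, filled with strictly rising or falling probe sets where fewer passed, the 5 of largest higher and lower difference for each hour against 1 h, the 10 brightest, the 2 brightest and the 3 of largest slope of each list, and the sex-linked and control probe sets. It took 140 probe sets of 136 genes. Genes outside it were chosen after their values were seen: Syt11, Syp, Cplx1, Marcksl1, Mag, Kl and Dbp in the results, and Per2, Per3, Nr1d2, Hba-a1, Hbb-b2, Bpgm, Slc4a1, Ace and Igfbp2 in the closing section.

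The trend was tested on simulated data of 7453 probe sets over 4 arrays, with 200 changed in each of 20 simulations. At slopes of 0.2, 0.4 and 0.8 log2 units per hour, 3.7%, 47.8% and 88% were recovered, with 5.2 false calls per simulation and 0 calls where nothing changed. Each simulated probe set had the same spread in all 4 arrays. In the data the SD of the log2 difference from the mean of the other 3 arrays was 0.578 at 1 h and 0.389 to 0.423 later. The trend rates therefore may not hold for these arrays. A simulated list of 25 probe sets with a slope of 0.2 was called in 100% of simulations, and 0.05 of 21 lists per simulation were called where nothing changed. These lists were tested at the preset correlation, on probe sets drawn independently with the same spread in each array. The rates do not carry over to lists whose probe sets move together, such as glutamate receptor genes (estimated correlation 0.414).

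Alternatives were quantile normalization, scaling to the same median, a floor at the 25th percentile, an offset in place of the floor, no filter, a filter at the 60th percentile, the brightest probe set of each gene, other codings of time, other variance priors, each array left out in turn, a threshold of 1.5-fold, and other references. The references that leave out the 1 h array, the fit of all 24 orders of the hours and the estimated correlation with an array left out were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.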

Results

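Gene expression was measured in the dentate gyrus of the hippocampus of young male C57BL/6J mice with single-channel oligonucleotide arrays. The 4 samples were handled controls that received no other treatment. Their RNA was taken 1, 2, 4 and 6 h after experimental mice of the same study had received their last shock, and those shocked mice were not analysed here. Each hour had 1 array, so a value at an hour has no replicate error, and any mean ± SD below runs over the 4 control arrays (n = 4). The labels do not say how many mice gave each RNA or whether RNA was pooled, so p-values rest only on these 4 samples. Those of the trend use the scatter around a line, with each variance moderated across probe sets. The comparisons below describe how far control transcript levels differed between these hours. The number of arrays limits the precision of every value.

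The brightest probe sets are given by intensity, which does not rank transcript levels between genes. Rpl41, a ribosomal protein gene, had the highest mean, an intensity of 54287 ± 6249 (SD, n = 4), and Gnas, the stimulatory G protein alpha subunit, 38909 ± 3177. Ncdn (neurochondrin), Apoe (the main lipid carrier of astrocytes), Rps28, Tuba1a, Cst3, Rps24, Prnp (the prion protein) and Basp1 followed, with means from 31246 down to 25382. Among synaptic and receptor genes, Dnm1, the dynamin of synaptic vesicle recycling, measured 23947 ± 309 on its brighter probe set, and Snap25, a protein of vesicle fusion, 19753 ± 1702. Gria2 and Gria1, AMPA-type glutamate receptor subunits, reached 10062 ± 273 and 6938 ± 1732, and Gabrb1, a GABA-A receptor subunit, 5686 ± 242.

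Genes of several cell types were measured. Calb1 (calbindin, abundant in granule cells) had an intensity of 2196 ± 178, and Neurod2, a neuronal transcription factor, 1661 ± 329. Among interneuron genes, the neuropeptide gene Cck measured 12645 ± 1395 and Gad1, which makes GABA, 4171 ± 104. The CA pyramidal list was led by Rgs14 at 3426 ± 514 and Nnat at 1970 ± 871, the astrocyte list by Apoe and Mt3 (22321 ± 3052). The myelin genes Mobp and Mbp reached 5430 ± 1279 and 4777 ± 818, the microglial genes Ctss and C1qc 2620 ± 302 and 1727 ± 238, and the vascular genes Ly6e and Bsg 14795 ± 839 and 4047 ± 1556. Ptgds, which makes prostaglandin D and is high in meninges, measured 10403 ± 4085. Pde1b and Penk, high in striatum, measured 2159 ± 517 and 1230 ± 200. Tubb3 and Stmn1, high in young neurons, measured 8137 ± 1102 and 4128 ± 1061. Of the sex-linked genes, the Y-linked Eif2s3y measured 188, 150, 187 and 125 at 1, 2, 4 and 6 h, Uty 63.9, 24.3, 81.8 and 105, and Kdm5d 69.6, 30.3, 35.9 and 46.4. Xist, expressed from the inactive X chromosome of females, measured 11, 14, 69.2 and 9.4, against a floor of 16.4. Only Eif2s3y of these was bright enough to be tested, so the sex-linked list was not tested as a group.

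The 1 h control array stood farther from the others than they stood from each other. Against the mean of the other 3 arrays, 528 of 7453 probe sets differed at least 2-fold at 1 h, 134 higher and 394 lower. The counts were 253 at 2 h, 210 at 4 h and 206 at 6 h. The control transcript Gapdh, a glycolytic enzyme, had a 3' to 5' intensity ratio of 4.88 at 1 h and of 1.13, 1.33 and 1.24 at 2, 4 and 6 h. Its 5' probe set read 7553 at 1 h and between 24943 and 26761 later, and its middle probe set 16969 at 1 h and between 28756 and 29275 later. The beta-actin ratio was 2.51 at 1 h and 1.83, 2.20 and 1.97 later, and the geometric mean of 9 spike-in probe sets was 6701 at 1 h and 4778, 5634 and 5077 later. The median SD between arrays was 0.24 on the log2 scale, or 1.18-fold, and 0.18 without the 1 h array. Pearson's r across probe sets, which are not independent replicates, was 0.92 to 0.93 for the 3 pairs with the 1 h array and 0.957 to 0.964 for the other 3 pairs.

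**Figure D1:**
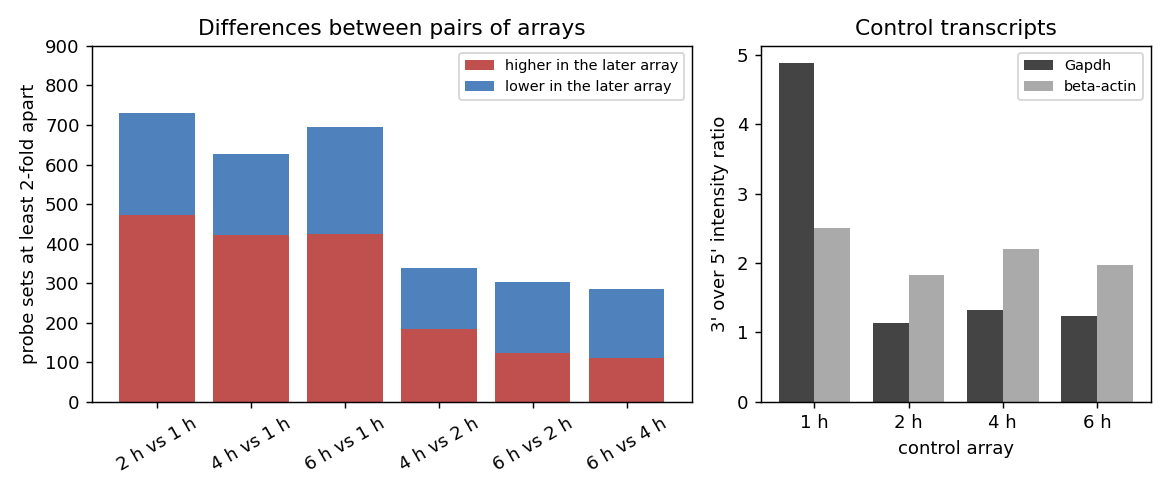
Left, the number of probe sets at least 2-fold apart (y axis) for each pair of control arrays, split into those higher and lower in the later array; right, the 3' to 5' intensity ratio of Gapdh and beta-actin in each array. The 3 pairs with the 1 h array hold 627 to 730 such probe sets and the other 3 pairs 286 to 339, and the Gapdh ratio is 4.88 at 1 h.

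At 2 h compared with 1 h, 730 of 7453 probe sets (9.79%) differed at least 2-fold, 473 higher and 257 lower. The 5 largest higher differences were those of Map2, Cttn, Gnaz, Sirpa and Akap1, each with a 1 h value near the floor of 16.4, so no fold is given. Map2, a dendritic microtubule protein, read 27.9 at 1 h and 496 at 2 h, Cttn (cortactin, which binds actin) 17.5 and 352, and Gnaz, a G protein subunit, 25.5 and 420. Sirpa, a membrane receptor, read 22.6 and 412, and Akap1, an anchor of protein kinase A, 20.7 and 342. Lower at 2 h were Hdac3, a histone deacetylase (779 and 72.6), Scx, a tendon transcription factor (701 and 69.7), Th, the enzyme that starts dopamine synthesis (182 and 21.8), Hoxa6 (326 and 42.4) and Grn, the progranulin gene (304 and 45). Other probe sets of these genes differed less: 1 more of Cttn (2932 and 3111) and Grn (628 and 637), and 2 more of Sirpa (855 and 1533, and 271 and 743) and Akap1 (158 and 117, and 488 and 647). With 1 array per hour these differences have no replicate check and no p-value, and the Gapdh ratio of 4.88 belongs to the reference array of all of them. Against the mean of the 4 h and 6 h arrays, a reference chosen after that ratio was seen, 235 probe sets differed, 113 higher and 122 lower. With no filter on dim probe sets, 1229 were higher and 1270 lower than at 1 h.

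At 4 h compared with 1 h, 627 probe sets (8.41%) differed at least 2-fold, 423 higher and 204 lower. Akap1, Cttn, Gnaz and Sirpa were again among the highest, at 307, 256, 326 and 273, and Gga1, a Golgi sorting adaptor, read 42.1 at 1 h and 490 at 4 h. The lower values were those of Ap2b1, an adaptor of clathrin-coated vesicles (298 and 38.6), Col1a1, a collagen chain (484 and 66.7), Ciita, the activator of MHC class II genes (305 and 45.4), Adh4 (366 and 55.5) and Gemin5 (242 and 38.5). Against the mean of the 2 h and 6 h arrays, chosen in the same way, 235 probe sets differed, 130 higher and 105 lower. With no filter, 1236 were higher and 1184 lower than at 1 h.

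At 6 h compared with 1 h, 696 probe sets (9.34%) differed at least 2-fold, 424 higher and 272 lower. Gnaz, Cttn, Sirpa and Akap1 stood high once more, at 440, 249, 281 and 243, beside Ttr, the transthyretin gene, at 3009. Lower were Scx (701 and 63.0), Cr1l, a complement regulator (406 and 40.3), Zfp771 (229 and 25.5), Bcl2l11, which promotes apoptosis (412 and 46.7), and Pdzk1ip1 (376 and 49.1). A second probe set of Cr1l read 136 and 129, and of Bcl2l11 246 and 162. The split moved with the scaling: 60.9% of the differing probe sets were higher as deposited and 71.4% when the arrays were scaled to the same median, which moves the 6 h array by 0.08 on the log2 scale and the 1 h array by -0.03. Against the mean of the 2 h and 4 h arrays, chosen in the same way, 203 probe sets differed, 65 higher and 138 lower. The filter turned the direction as well: with none, 1049 were higher and 1413 lower than at 1 h (42.6% higher), and with a filter at the 60th percentile 77.9% were higher.

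Ttr, the thyroid hormone carrier that the choroid plexus makes in bulk, rose across the hours. Its intensity was 225 at 1 h, 444 at 2 h, 1258 at 4 h and 3009 at 6 h, which is a slope of 0.74 ± 0.05 (SE) log2 units per hour over the 4 arrays. It was the only one of 7453 probe sets past the threshold in limma, with an adjusted p of 0.0232, and 0 probe sets passed it downward. At an unadjusted p under 0.05 there were 328 probe sets in limma, 152 with positive and 176 with negative slopes, where chance gives 373. With the arrays scaled to the same median, 287 of 395 such slopes were positive. The count was 1000 without the 2 h array (624 positive), 166 without the 4 h array and 667 on the log2 of the hour. The call for Ttr was lost without the 4 h array (adjusted p = 0.15 in limma) and without the 6 h array (adjusted p = 0.998). It held without the 1 h array (slope 0.69, limma adjusted p = 0.00072), in a fit with fewer residual degrees of freedom. It was also lost in limma with no filter on dim probe sets (adjusted p = 0.812), with late against early hours (0.956) and with a variance prior without a trend on intensity (0.439).

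Other genes with steadily higher or lower values did not pass the test, each with an adjusted p of 0.874 in limma. The largest positive slopes among them were those of Capn1, a calcium-activated protease (72.0, 97.8, 425 and 485 at 1, 2, 4 and 6 h), Stard10, a lipid transfer protein (55.2 to 466), Zbtb17, a transcription factor (66.5 to 470), Rbms2, Sapcd1, Rab3b, Fxyd7, Vamp2 and Clcn1. Rab3b, a GTPase of secretory vesicles, went from 82.1 to 420, and Fxyd7, a regulator of the sodium pump, from 111 at 1 h to 566 at 2 h and 677 at 6 h. The largest negative slopes were those of Pdzk1ip1 (376 to 49.1), Bcl2l11 (412, 238, 153 and 46.7), Zcchc7, Tubb4b, a tubulin (267 to 49.9), Htr1a, a serotonin receptor (212 to 51.0), Gcdh, Kcnn1, a potassium channel (606 to 131), Flg, Cldn8 and Srsf4. Second probe sets had slopes nearer 0, at 0.04 for Vamp2, -0.12 for Bcl2l11, -0.05 for Zcchc7, -0.08 for Gcdh and 0.07 for Srsf4. Values ran strictly upward over the hours in 331 probe sets and strictly downward in 446, together 10.4% where chance order gives 8.33%. That chance value takes the arrays as alike, and the 1 h array, at an end of the order, stood apart. The excess is therefore not evidence of a trend over the hours.

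**Figure D2:**
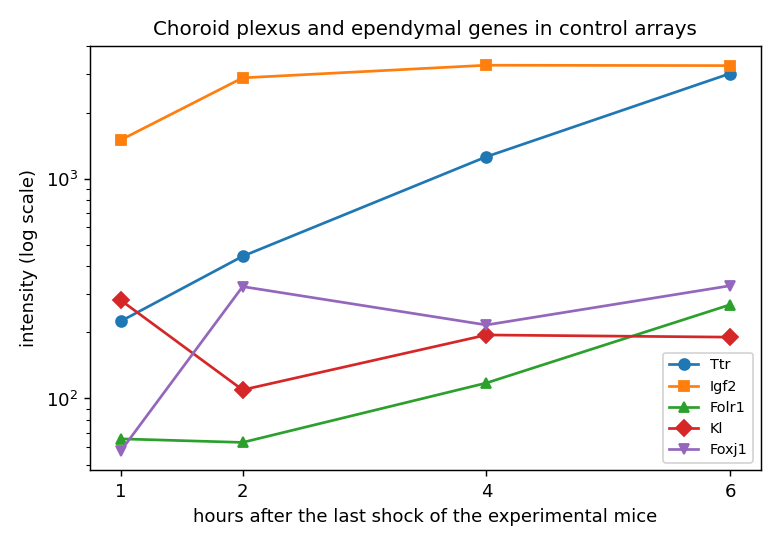
Intensity on a log axis (y) against the hour (x) for 5 choroid plexus and ependymal genes, 1 point per control array. Ttr goes from 225 to 3009 while Igf2 stands between 2876 and 3282 from 2 h on. Genes of the list whose values fell from 2 h to 6 h are not drawn.

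Among the 21 gene lists tested for a shared slope, 4 passed, all with higher slopes than those of other genes. Synaptic vesicle and release genes had 18 of 25 slopes positive (camera adjusted p = 0.00173 in limma, and 0.751 with an estimated correlation). Their median log2 deviation from the mean of the 4 arrays was -0.345, 0.154, -0.014 and 0.15 at 1, 2, 4 and 6 h. At 1, 2, 4 and 6 h, Syt11 read 345, 2488, 2112 and 2211, and Syp, the vesicle protein synaptophysin, 569, 1503, 1333 and 1810. Cplx1 read 846, 3283, 1675 and 3295, and Vamp1 26.7, 250, 201 and 312. Syt11, Syp and Cplx1 were chosen after their values were seen. At 1 h, 18 of the 25 probe sets lay below the mean of the other arrays and 7 above it. The brightest probe sets of the list were not low at 1 h. Snap25 read 22175, 18591, 18541 and 19705, and Dnm1 24263, 23538, 24080 and 23908 on its brighter probe set. The brighter probe set of Vamp2 read 10943, 11447, 12183 and 12371. The glutamate receptor list had 11 of 13 slopes positive (camera adjusted p = 0.00224 in limma, and 0.751 with an estimated correlation). Its median deviation was -0.687, 0.187, 0.266 and 0.234. Its 13 probe sets were of 9 genes, and those of Gria2 differed, with slopes of 0.012, 0.146 and -0.092. Grik5, a kainate receptor subunit, read 454, 1747, 1646 and 1841, and 337, 111, 257 and 181 on a second probe set. The NMDA receptor subunit genes Grin2b and Grin2c read 46.0, 353, 198 and 276, and 314, 645, 693 and 681. Both lists lost the call without the 1 h array, whose Gapdh ratio was 4.88 (limma adjusted p = 0.448 for synaptic and 0.761 for glutamate receptor genes). Adjusted over the list alone, 0 probe sets of either list passed.

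The choroid plexus and ependymal list had 8 of 11 slopes positive (camera adjusted p = 0.00391 in limma, and 0.751 with an estimated correlation). Its median log2 deviation from the mean of the 4 arrays was -0.467, 0.18, 0.183 and 0.052 at 1, 2, 4 and 6 h. Its members were Ttr, Folr1, a folate receptor (65.5, 63.1, 118 and 267), Foxj1, a factor of motile cilia (57.7, 323, 216 and 326), and Igf2 (1501, 2876, 3282 and 3269) among others, while Kl (klotho) read 280, 109, 195 and 190. Adjusted over the list alone, 1 probe set passed, that of Ttr. The immature neuron and proliferation list had 16 of 25 slopes positive (camera adjusted p = 0.0258 in limma, and 0.751 with an estimated correlation). Adjusted over that list alone, 0 probe sets passed. Stmn1, which destabilises microtubules, read 2665 at 1 h and 4956 at 6 h, and Marcksl1 1500 and 2245. The probe sets of Mcm3, a replication gene, had slopes of -0.22 and 0.13. Without the 1 h array the choroid list lost its call (limma adjusted p = 0.345) and the immature neuron list kept it (0.0319; adjusted p = 0.909 with an estimated correlation). The latter was lost without the 2 h, the 4 h or the 6 h array (0.105, 0.107 and 0.116 in limma). With no filter on dim probe sets, the choroid list (limma adjusted p = 0.478) and the immature neuron list (0.0892) lost their calls. By fry, which asks whether a list's genes move 1 way on balance, 0 of the 21 lists passed, with a lowest adjusted p of 0.748 in limma. The estimated correlation of the immature neuron list was 0.012, near the preset 0.01, yet its camera p in limma went from 0.00492 to 0.11. With so few residual degrees of freedom, a list not passing by an estimated correlation or by fry argues neither for nor against a shared slope.

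The other 17 lists did not pass, and in each of them 0 probe sets passed adjusted over the list alone. Of the lists linked to handling, stress and time of day, immediate early genes had 16 of 22 slopes positive, activity-induced effector genes 6 of 20, glucocorticoid-responsive genes 6 of 23, circadian clock genes 13 of 22, and heat shock and chaperone genes 14 of 30. Jund and Jun, immediate early genes, measured 12282 ± 906 and 1543 ± 110, and Mt2 and Mt1, metallothioneins that glucocorticoids induce, 16540 ± 1256 and 12702 ± 1476. Per1, a clock gene that stress hormones also induce, read 303, 156, 374 and 517, and Dnajb5, a chaperone gene, 35.8, 245, 132 and 184. Inhba, an activity-induced gene, read 237, 124, 267 and 70.4, and Cdkn1a 120, 279, 161 and 62.6 on 1 probe set and 125, 191, 97.1 and 178 on another.

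Of the cell type lists, granule cell markers had 11 of 15 slopes positive, CA pyramidal markers 6 of 12, interneuron markers 11 of 15, astrocyte markers 11 of 26, oligodendrocyte markers 10 of 21, microglia and macrophage markers 8 of 21, endothelial and mural markers 8 of 21, meningeal and fibroblast markers 9 of 15, and thalamic and striatal markers 7 of 11. Prox1, the granule cell transcription factor, read 71.6, 278, 155 and 232, and Calb2 (calretinin) 663, 1265, 1229 and 1427. Aqp4, the astrocyte water channel, read 1751 at 1 h and 2692 at 6 h, Cd53, a leukocyte gene, 221 and 111, and Flt1, an endothelial receptor, 328, 65.8, 186 and 55.3 at the 4 hours on 1 probe set and 352, 361, 242 and 212 on another. The oxidative phosphorylation list had 32 of 74 slopes positive, the cytosolic ribosomal protein list 11 of 33 and the GABA-A receptor list 3 of 6. Cycs (cytochrome c) read 744, 585, 488 and 435, Rps13 537, 328, 454 and 144, and Gabrd, a GABA-A receptor subunit, 20.8, 190, 217 and 194. The ribosomal list takes its members by name and holds 2 tested probe sets of S6 kinases, which phosphorylate a ribosomal protein, among them Rps6kb2 (240, 128, 270 and 288). Without the 1 h array, oligodendrocyte markers had lower and oxidative phosphorylation genes higher slopes than other genes (limma adjusted p = 0.000724 for each; adjusted p = 0.909 for each with an estimated correlation). Ribosomal protein genes passed downward without the 2 h array (limma adjusted p = 0.0466; adjusted p = 0.889 with an estimated correlation) and meningeal markers upward without the 6 h array (adjusted p = 0.0169; adjusted p = 0.801 with an estimated correlation).

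Single arrays differed in cell type and function lists, given as the median log2 difference of a list from the mean of the other 3 arrays. At 1 h the glutamate receptor list stood at -0.92 (0.53-fold), with 11 of 13 probe sets below the other arrays, the choroid list at -0.62 and the synaptic list at -0.46. At 2 h these 3 lists stood at 0.25, 0.24 and 0.20. At 4 h the choroid list stood at 0.24, with 9 of 11 above, and the synaptic list at -0.02. The oligodendrocyte markers at 2 h stood at 0.33 (1.26-fold), with 17 of 21 above. Mobp, Mbp and Mag, genes of myelin, read 6907, 5931 and 627 there, against 4428, 4590 and 444 at 4 h, while a second probe set of Mag read 104 and 145. In that array clock genes stood at 0.32 with 14 of 22 above, although Per1 (-1.32) and Dbp (-0.93) were far below. Glucocorticoid-responsive genes stood at 0.30 with 15 of 23 above and heat shock genes at 0.24 with 20 of 30 above, and oxidative phosphorylation genes were low at -0.12 with 57 of 74 below. At 4 h the meningeal and fibroblast markers stood at 0.48 (1.39-fold), with 12 of 15 above, among them Ptgds (14999, against 12282 at 2 h and 8655 at 6 h) and Pcolce (441 against 288 and 282), while Col1a1 was low. In the same array glutamate receptor genes stood at 0.36 with 12 of 13 above, CA pyramidal markers at 0.30, thalamic and striatal markers at 0.27 and glucocorticoid-responsive genes at -0.19. At 6 h glutamate receptor genes stood at 0.31, with 11 of 13 above, synaptic genes at 0.20, with 21 of 25 above, and immature neuron genes at 0.20. Granule cell markers stood at 0.165, with 10 of 15 above. Endothelial and mural markers stood at -0.23, with 16 of 21 below, and CA pyramidal markers at -0.19, with 8 of 12 below. The low 1 h values of the glutamate receptor, choroid and synaptic lists enter the mean that each later array is set against. Each of these signs was the same after quantile normalization and after scaling to the same median, but the sizes at 6 h moved. Endothelial and mural markers stood at -0.16 and -0.12, synaptic genes at 0.22 and 0.31, and immature neuron genes at 0.22 and 0.32. Glutamate receptor genes stood at 0.28 and 0.42, granule cell markers at 0.14 and 0.28, and CA pyramidal markers at -0.07 and -0.08. No test applies to a single array. Among 10000 random lists matched on mean intensity, the medians of many lists lay at percentile 100. At 2 h these were oligodendrocyte, glucocorticoid-responsive, heat shock and synaptic genes. At 4 h they were meningeal and glutamate receptor genes, and at 6 h glutamate receptor and synaptic genes. Glutamate receptor and synaptic genes at 1 h lay at percentile 0. Random lists draw probe sets singly, while the oligodendrocyte list holds 21 probe sets of 14 genes. Lists whose probe sets move together reach extreme percentiles more readily, so the percentiles describe these arrays only.

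**Figure D3:**
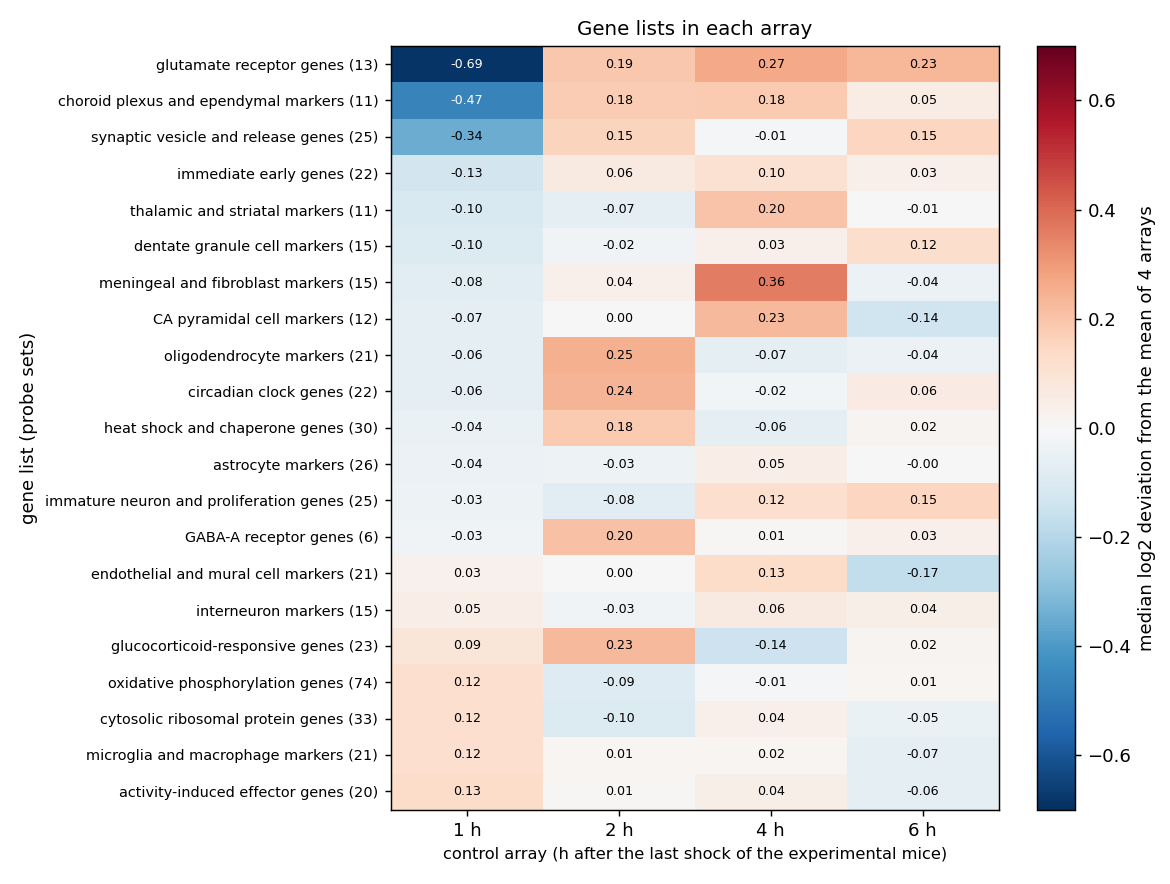
Median log2 deviation from the mean of the 4 arrays for each of 21 gene lists (rows, with the number of probe sets) in each control array (columns), with the value printed in each cell. The lowest cell is the glutamate receptor list at 1 h (-0.69), and the oligodendrocyte list is highest at 2 h (0.25).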

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

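Of the tests here, those on probe sets of the same gene and those on Ttr without the 1 h array and on choroid plexus genes were chosen after the result was seen, and so was the use of all 24 orders of the hours. The quantile test and the test of 12 orders were not.

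The 1 h array stood apart from the other 3. Its Gapdh 3' to 5' ratio of 4.88 lay far from theirs, and so did the median of its glutamate receptor list, at -0.69 on the log2 scale from the mean of the 4 arrays. Of 140 named probe sets, 22 had an array far from the other 3, which was the 1 h array in 16, the 2 h array in 1, the 4 h array in 3 and the 6 h array in 2. Over all tested probe sets the share was 8.63%, where chance gives 5%, with 5.23% for the 1 h array and 1.01 to 1.37% for each of the others. Many of the named genes were chosen for large slopes or differences, which raises their share.

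An array-wide difference in scaling is argued against: after quantile normalization the 1 h array still had 2.22 times as many probe sets at least 2-fold from the mean of the others as the next array. Less complete RNA or cDNA in the 1 h sample may be a cause, but it cannot be told apart from a noisier hybridization. The SD of differences between probe sets of the same gene at 1 h was 1.44 times the next largest. The overall deviation of that array was already 1.37 times the next largest. The SD ratio met the first bound set for this cause. A second bound, relative to the overall deviation, was added after both ratios had been seen, and it was not met. The beta-actin ratio of 2.51 lay near the 2.20 of the 4 h array, and the spike-in mean, highest at 1 h at 1.40 times the 2 h array against 1.18 at 4 h and 1.06 at 6 h, did not lie far enough from the others to count as apart. Transcript levels that differed at 1 h stay open as well, since the deviations of probe sets of the same gene correlated across pairs with r = 0.124 (0.065, 0.035 and 0.021 in the 2, 4 and 6 h arrays), between the values set for and against. The design has no other group, so what might have changed transcript levels at 1 h was not tested.

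At 1 h the outlying values were those of Fxyd7 (111), Gnaz (25.5), Wee1 (31.9), Grin2c (314), Gabrd (20.8), Igf2 (1501), Bsg (1728) and Tef (2701), all lower than in the other arrays, and Nr1d1 (767), which was higher. On 1 of several probe sets, Sirpa (22.6), Aqp4 (217), Cttn (17.5), Akap1 (20.7), Hspa4 (81.2), Pdia6 (102) and Grik5 (454) were also outlying and lower. The other tested probe sets of Sirpa and Aqp4 were lowest at 1 h too. Each of the last 5 genes had another probe set that was not lowest at 1 h. The brightest of Hspa4 read 4098 there and 3184 to 3398 later, and 1 of Pdia6 449 there and 238 to 369 later.

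In the 2 h array Th was low at 21.8, and the median of the oligodendrocyte list was high at 0.25 on the log2 scale from the mean of the 4 arrays. In the 4 h array Col1a1 was low at 66.7 and Ptgds was high at 13501 on 1 of its probe sets. Xist read 69.2 at 4 h, with the other 3 arrays under the floor of 16.4. In the 6 h array 1 probe set of Txnip was low at 141 and 1 of Srsf4 at 85.5, while the other of each read 359 and 641 and was not lowest there.

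Ttr rose over the hours while other choroid plexus genes went both ways. The rise of Ttr did not rest on the 1 h array alone, since the slope over the 2, 4 and 6 h arrays was 0.69. Ttr was picked for its slope over these same arrays, so this is no independent support for a trend. The 12 planned orders of the hours are too few for a share under 0.05: the real order called 1 probe set and the highest other 0. All 24 orders, fitted after those 12 had been seen because the hours are unevenly spaced, gave the same values, 1 and 0, and are not used to settle the matter. More choroid plexus tissue in the later samples may be the cause but cannot be told apart from a rise of Ttr alone. The 8 choroid plexus probe sets other than Ttr that the meningeal list does not share had a median change from 2 h to 6 h of -0.15 (percentile 35.1 of random lists). Of these changes 3 were above 0 and 5 below, with Folr1 at 2.08, Kl at 0.80, Foxj1 at 0.01 and Ace at -0.61. With the 2 shared ones, Igf2 and Igfbp2, the median was also -0.15 (percentile 22.2).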

How the results depend on the processing

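Of the tests here, the references that leave out the 1 h array and the estimated correlation with an array left out were chosen after the data were seen. The count of 1 trend (Ttr) became 0 with no filter on dim probe sets, with late against early hours and with a variance prior without a trend on intensity, and ran from 0 to 1 when each array was left out, 0 without the 4 h or the 6 h array. The adjusted p of Ttr in limma ran from 0.00072 to 0.998 over its 16 alternatives, its slope stayed positive, and the cause of the losses was not tested beyond the arrays left out. The count of 4 gene lists became 2 with no filter. With an estimated correlation, with all arrays or any 1 left out, or by fry, tests with few residual degrees of freedom, it became 0. It ran from 3 to 4 when each array was left out, not always of the same lists: without the 1 h array 3 of the 4 were lost and 2 entered, and without the 2 h or the 6 h array 1 was lost and 1 entered, and without the 4 h array 1 was lost. The median SD ran from 0.182 to 0.246 when each array was left out.

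The 2-fold counts at 2, 4 and 6 h against 1 h were 730, 627 and 696. They became 2499, 2420 and 2462 with no filter, where dim probe sets enter, and 249, 204 and 231 with a filter at the 60th percentile. With the brightest probe set of each gene, fewer were tested and they were 477, 435 and 445. At 1.5-fold they were 1897, 1785 and 1770. Against the mean of the other 3 arrays they were 253, 210 and 206, and against the mean of the 2 arrays apart from 1 h 235, 235 and 203. Leaving out an array gives no value for a difference from it. No paired analysis was possible because the series has 1 group. Of 2083 slopes of named probe sets under alternatives, 88 had the opposite sign. Probe sets near the floor of 16.4 limit what dim genes can show.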

Other observations

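The test on clock genes here was chosen after their values were seen.

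Of the 9 probe sets of the erythrocyte list, 4 passed the intensity filter, and those were too few to test as a group. Hba-a1, a hemoglobin alpha chain, measured 2738 ± 666 (SD, n = 4) and ran from 1931 at 6 h to 3397 at 4 h, while Hbb-b2 measured 440 ± 18.7. Bpgm, an enzyme of red cell metabolism, measured 988 ± 71.3 and Slc4a1, the red cell anion exchanger, 108 ± 37.1.

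Clock genes differed unevenly between 2 h and 6 h. Per1 read 156 at 2 h and 517 at 6 h, a log2 change of 1.73, and Dbp 312 and 702, a change of 1.17, while Per2 went the other way by -0.98. At 1 h, Per1 read 303 and Dbp 708, so both were lowest in the single 2 h array. Dbp was about as high at 1 h as at 6 h, and its change from 2 h is not a rise over all the hours. A hypothesis is that tissue taken at different times of day may carry a daily rhythm, since the labels give hours after shock and no time of day. The median change of Dbp, Per1, Per2, Per3, Nr1d1, Nr1d2 and Tef was 0.15, at percentile 91.6 of random lists, with 4 above and 3 below 0. That median lies between the values set for and against, so a daily rhythm cannot be told apart from differences between single arrays. The test asked only whether these genes moved together. A rhythm that raised some of them and lowered others would not show in a shared median.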
